A study of Mus musculus with 40 samples.

How the data were processed

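RNA was measured in 40 libraries of macrophages and neutrophils sorted by flow cytometry from the decidua and the uterus of pregnant mice. Per the labels' protocols, S100B or PBS was injected into the amniotic cavity at 16.5 days post coitum and tissue was collected 16 hours later. RNA was isolated with PicoPure columns, cDNA was made by Smart-seq2 and libraries with Nextera, and the neutrophil RNA of 2 to 4 animals was combined per library. Groups were read from the labels as tissue, cell type, genotype and treatment, and the replicate number is the number in the library's title. The series was deposited as 2 tables of 20 libraries, PBS in 1 and S100B in the other, and all 40 columns were used.

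The deposited values are expected counts, whole-number estimates of reads per Ensembl gene with no normalization. Per the submitters' processing notes the authors quantified reads with Salmon against GRCm38. The Salmon version, the annotation, the way transcripts were summed to genes and the rounding are not given in the sources used here. The 2 tables hold the same 29628 genes and were joined by Ensembl identifier. Symbols and positions came from GENCODE release M21 (GRCm38), which named 29306 of the genes, and the 322 others held 0.126% of the counts and were kept in the tests. The whole-number form and the unequal library totals were checked before any test.

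Macrophage libraries held 47081615 to 56367164 counts and neutrophil libraries 38677930 to 53360240. The 10 most abundant genes took 14.9% to 22.5% of the counts in macrophages and 17.8% to 25.2% in neutrophils. The mean correlation of a library's log2 CPM with the other libraries of its cell type was 0.888 to 0.948 in macrophages and 0.623 to 0.767 in neutrophils. Counting error was therefore small beside the spread between libraries, with a biological coefficient of variation of 0.492 in macrophages and 1.34 in neutrophils.

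Macrophages and neutrophils were fitted apart, each with 8 groups and 1 coefficient per group. Genes were kept by filterByExpr with the groups (17154 in macrophages, 15390 in neutrophils), counts were scaled by the trimmed mean of M values (TMM), and edgeR's robust quasi-likelihood F test gave each comparison (edgeR 4.0.16, limma 3.58.1, R 4.3.3). The residual degrees of freedom were 16 and 8. Adjusted p values are Benjamini-Hochberg values over the genes of 1 comparison, with 0.05 as the threshold, and were not adjusted again across comparisons. Group levels are means ± standard deviations of TMM-scaled CPM, log2 fold changes are edgeR's with a prior count of 0.125, and their standard errors come from the quasi-likelihood fit. The 24 planned comparisons were S100B against PBS within each genotype, Nlrp3-/- against Nlrp3+/+ within each treatment, and the genotype difference of the S100B response, each per tissue and cell type, and for each cell type decidua against uterus in PBS-treated Nlrp3+/+ libraries and the tissue difference of the S100B response. The 8 comparisons added later are means of the group differences over tissues, genotypes or treatments from the same fits.

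Gene lists were 18 function lists and 14 marker lists of cell types, 638 genes in all, of which Gbp5, Gbp6, Ifi30 and Ahsp have no entry in the tables. Each list was tested with camera of limma on log2 CPM with a prior count of 2, once with the preset correlation of 0.01 between genes and once with a correlation estimated from the libraries. Camera p values were adjusted over the 32 lists of a comparison, or 33 where genotypes were compared and the genes within 10 Mb of Nlrp3 formed a list of their own. An adjusted p over the list alone is a Benjamini-Hochberg value of edgeR's p values over that list's members. Marker sums are sums of CPM over the members of a list.

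Genes named in the text followed a rule. Nlrp3 came first, then the called genes with an average log2 CPM of at least 3, no overlap between the libraries of the 2 groups in 2-group comparisons, and a symbol of a known gene that is not a pseudogene. The largest changes among them were eligible, up to 12 in each direction for S100B in Nlrp3+/+ and up to 6 in each direction elsewhere. For each list described, up to 4 members with the smallest p could be named, and Il1b, Il1a, Il18, Casp1, Pycard, Gsdmd, Tnf, Il6, Cxcl1, Cxcl2 and Ptgs2 wherever they were tested. Gm28900 and Gm29487 fall outside the rule and were chosen after their values were seen, because they were among 5 or fewer called genes, and so do NK markers listed among the flagged results.

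The scripts were tested on counts simulated with the means, library sizes and spread of real libraries and 200 genes changed 2-fold or 4-fold. Recovery was not split by expression level. For S100B against PBS in Nlrp3+/+ decidual macrophages edgeR recovered 48% of the 2-fold and 97% of the 4-fold changes (16749 genes fitted). Of its 153 calls 4 were on unchanged genes. In the genotype comparison over all macrophages it recovered 94% and 99% (16717 genes fitted), with 16 of 229 calls on unchanged genes. In the S100B comparison of Nlrp3+/+ decidual neutrophils it recovered 0% of either size, and in the genotype comparison over all neutrophils 2% and 18%. DESeq2 1.42.0 recovered 62% and 99% in the first of these. Its calls on unchanged genes, in the same order of comparisons, were 33 of 198, 69 of 284, 461 of 481 and 670 of 746.

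Alternatives tried were DESeq2 size factors in the edgeR fit, no expression filter beyond a count above 0, a DESeq2 Wald test, a fit of the tissue's 4 groups or of the compared groups only, the replicate number as a block in tissue comparisons, and leaving out each library in turn. After the data had been seen, the replicate number as a random effect in limma's voom and the leave-one-out test of every passing list were added, as were the inflammasome list without Nlrp3 and the erythroid and stroma sums of neutrophils without the highest library. Other splits of the libraries were run through the same test, as described below. Nlrp3 folds between genotypes carry a 95% Poisson interval of pooled counts, with 3 counts as the floor where a group had none. Pairs of replicates were compared by a chi-square per gene over genes with at least 20 counts in the pair.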

Results

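Sterile inflammation of the amniotic cavity can start labour before term, and the series asked whether the inflammasome sensor NLRP3 is needed when the alarmin S100B is the trigger. Pregnant mice with NLRP3 (Nlrp3+/+) or without it (Nlrp3-/-) received S100B or PBS into the amniotic cavity at 16.5 days post coitum. Decidua and uterus were taken 16 hours later, and macrophages and neutrophils were sorted from each tissue. The 40 RNA libraries formed 16 groups, every combination of 2 tissues, 2 cell types, 2 genotypes and 2 treatments. Macrophage groups held 3 libraries and neutrophil groups 2, and each neutrophil library combined RNA of 2 to 4 animals. Counts for 29628 genes were deposited as 2 tables, 1 with every PBS library and 1 with every S100B library, so a treatment effect and a difference between tables cannot be told apart. The 24 planned comparisons, the gene lists, their main tests and the rule that names genes were set before the data were examined. Another 8 comparisons, which pool tissues, genotypes or treatments, and some checks were added after the data had been seen. So were Gm28900 and Gm29487, named outside the rule.

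Macrophage marker transcripts summed to 36108 ± 4311 CPM (counts scaled to the library total) in decidual macrophages and 36854 ± 4424 CPM in uterine macrophages (mean ± standard deviation, n = 12 each). Neutrophil markers summed to 105090 ± 32339 CPM in decidual and 52731 ± 6525 CPM in uterine neutrophils (n = 8 each), against 234 ± 58.0 and 261 ± 175 CPM in the macrophages. Neutrophil libraries also held macrophage markers, 7509 ± 1737 CPM in decidua and 14873 ± 4364 CPM in uterus, and erythroid markers at 9996 ± 18284 and 6151 ± 4045 CPM. Without the highest library, Nlrp3+/+ S100B replicate 5, decidual neutrophils held 3586 ± 2575 CPM of erythroid markers, so the order of the tissues turns on it. Macrophage libraries had 15815 to 18710 genes detected and neutrophil libraries 11540 to 15269. No 2 replicates of a group matched within sampling noise, with a chi-square per gene of 43.0 to 894 over the 32 pairs. Replicate 9 of the Nlrp3+/+ S100B uterine macrophages had the fewest genes of any macrophage library, and replicate 7 of the Nlrp3-/- PBS uterine neutrophils had the fewest of all.

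Nlrp3 transcripts separated the genotypes in every library, from 14.9 to 535 CPM in the 20 Nlrp3+/+ libraries against 0 to 8 reads in each of the 20 Nlrp3-/- libraries. Group means in Nlrp3+/+ macrophages were 67.0 ± 11.3 CPM (PBS) and 51.0 ± 10.3 CPM (S100B) in decidua, and 51.3 ± 9.24 and 49.0 ± 27.6 CPM in uterus (n = 3 each). Nlrp3+/+ neutrophils held 360 ± 185 and 354 ± 304 CPM in decidua, and 158 ± 37.1 and 141 ± 30.5 CPM in uterus (n = 2 each). Nlrp3-/- decidual macrophages had 1 read in the PBS group, 11337-fold below Nlrp3+/+ (95% counting interval 2034 to 447820), and 0 reads in the S100B group, at least 2768-fold below with 3 counts as the floor. Nlrp3-/- uterine macrophages had 5 reads (PBS, 1561-fold lower, 669 to 4809) and 7 reads (S100B, 1019-fold lower, 494 to 2535). Nlrp3-/- decidual neutrophils had 8 reads (4000-fold lower, 2030 to 9266) and 10 reads (3148-fold lower, 1712 to 6566). Nlrp3-/- uterine neutrophils had 10 reads (1585-fold lower, 862 to 3307) and 3 reads (4794-fold lower, 1640 to 23251). These intervals cover counting error only and not the spread between libraries. Nlrp3 lies on chromosome 11 (59541568 to 59566956, forward strand, GRCm38).

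**Figure D1:**
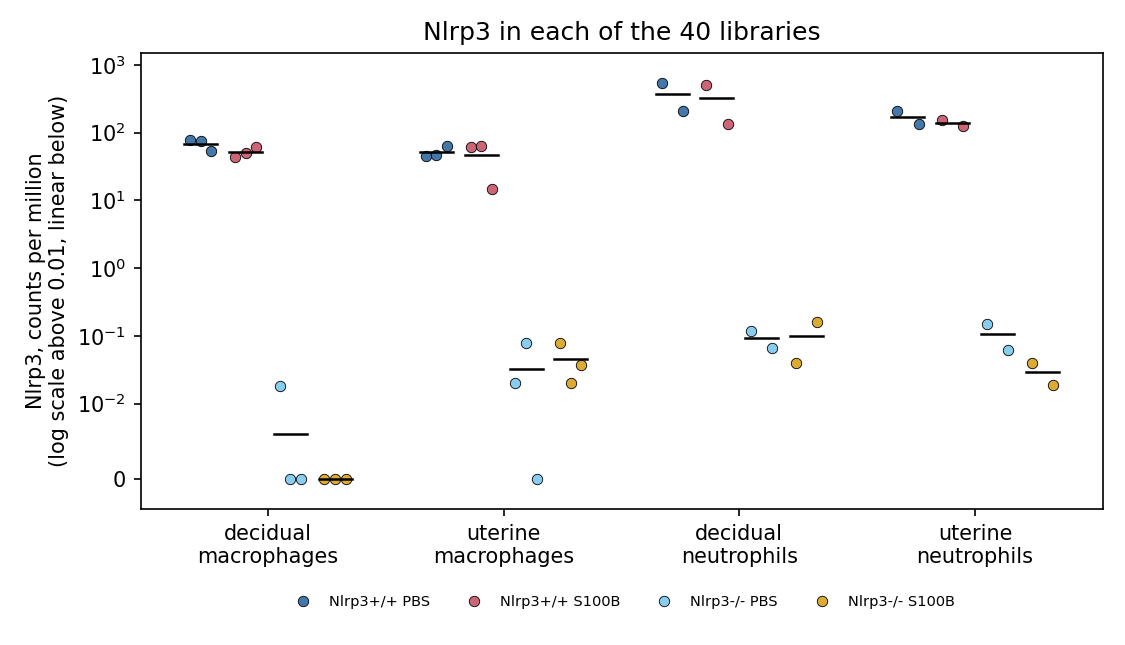
Nlrp3 in CPM in each of the 40 libraries, by cell population, genotype and treatment. The Nlrp3+/+ libraries run from 14.9 to 535 CPM and the Nlrp3-/- libraries from 0 to 8 reads, and the bars are group means.

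No rise of cytokine transcript was detected after S100B in Nlrp3+/+ decidual macrophages. Il1b, which encodes the interleukin 1 beta precursor that caspase 1 cleaves, stood at 1095 ± 107 CPM after S100B and 1294 ± 256 CPM after PBS (n = 3 each, log2 fold change ± standard error -0.24 ± 0.21, edgeR). Tnf, an early product of activated macrophages, stood at 106 ± 29.3 and 137 ± 25.8 CPM (log2 -0.37 ± 0.22). Of 24 inflammatory cytokine genes 11 were higher, and the list did not pass (camera adjusted p = 0.712). Cell cycle genes fell as a list, 30 of 34 of them lower (median log2 -0.20, camera adjusted p = 3.34e-05, adjusted p = 0.683 with an estimated correlation). Pcna, the sliding clamp of DNA replication, stood at 133 ± 20.9 against 160 ± 11.7 CPM. Erythroid markers rose (median log2 1.43, camera adjusted p = 0.000335, adjusted p = 0.683 with an estimated correlation). So did trophoblast markers (0.0421, adjusted p = 0.683 with an estimated correlation), with the spongiotrophoblast transcript Tpbpa at 56.6 ± 70.0 against 2.69 ± 2.71 CPM. Monocyte markers rose as well, to 3829 ± 339 from 2885 ± 144 CPM (9 of 10 higher, camera adjusted p = 0.00565, adjusted p = 0.683 with an estimated correlation). B cell markers fell and homeostatic macrophage genes rose (both with a camera adjusted p = 0.0421, adjusted p = 0.683 and 0.929 with an estimated correlation). Among 17154 genes edgeR called 0, with 557 at an unadjusted p below 0.05 where chance gives 858, and DESeq2 called 24. Camera passed 6 of 32 lists with its preset correlation of 0.01 and 0 with a correlation estimated from the libraries. In counts simulated on this comparison edgeR recovered 48% of 2-fold changes, so such a rise is not excluded. Without S100B replicate 8 the cell cycle list lost its call (adjusted p = 0.534), and the trophoblast list lost it without PBS replicate 2 (0.576) or S100B replicates 7 (0.714) and 8 (0.0801). Of 6 leave-one-out fits, 3 lost the call of the monocyte list (up to 0.131), 5 that of the B cell list (up to 0.329) and 4 that of the homeostatic list (up to 0.767), which reversed in 1 of them.

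In the uterus, Nlrp3+/+ macrophages after S100B carried more transcript of dividing cells and less of the glycolytic enzymes. Top2a, which untangles replicated DNA, stood at 69.6 ± 19.1 CPM after S100B and 35.2 ± 9.10 CPM after PBS (n = 3 each, log2 0.99 ± 0.26). Tk1, a thymidine kinase of S phase, stood at 92.9 ± 22.1 and 59.5 ± 9.08 CPM (log2 0.64 ± 0.18). Bnip3, a mitochondrial protein induced by low oxygen, stood at 17.1 ± 1.31 and 36.1 ± 20.4 CPM (log2 -1.08 ± 0.30). Il1b stood at 926 ± 145 and 904 ± 190 CPM (log2 0.04 ± 0.21, adjusted p = 0.958). The cell cycle list rose and the glycolysis and hypoxia list fell, both with a camera adjusted p = 9.75e-05 (adjusted p = 0.961 with an estimated correlation for both). The oxidative phosphorylation list rose (camera adjusted p = 0.0247, adjusted p = 0.961 with an estimated correlation), and 26 of its 36 genes were higher. edgeR called 0 genes with 1947 at an unadjusted p below 0.05 and a smallest adjusted p of 0.236, DESeq2 called 79, and without S100B replicate 8 edgeR called 8. PBS replicate 3 carried part of this picture, because without it the glycolysis list (adjusted p = 0.235) and the oxidative phosphorylation list (0.442) lost their calls, the second also without S100B replicate 9 (0.678). The type I interferon list fell (camera adjusted p = 0.0389, adjusted p = 0.961 with an estimated correlation). Yet without PBS replicate 3 it rose (adjusted p = 6.35e-06), and without S100B replicates 7 (0.800) or 8 (0.570) it lost its call.

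Pooling tissues gave more libraries per side without an Il1b difference. Il1b stood at 1011 ± 147 CPM after S100B and 1099 ± 294 CPM after PBS in all Nlrp3+/+ macrophages (n = 6 each, log2 -0.10 ± 0.15, edgeR adjusted p = 0.813). Over both genotypes it stood at 1027 ± 136 and 992 ± 266 CPM (n = 12 each, log2 0.07 ± 0.10, adjusted p = 0.891). Cxcl1, a chemokine that draws neutrophils, stood at 149 ± 41.9 and 114 ± 33.9 CPM over both genotypes (log2 0.37 ± 0.14, adjusted p = 0.777). Glycolysis genes fell in Nlrp3+/+ macrophages (camera adjusted p = 0.000129, adjusted p = 0.959 with an estimated correlation) and over both genotypes (0.000236, adjusted p = 0.711 with an estimated correlation), 22 of 26 lower each time. Decidual stroma and fibroblast markers rose over both genotypes, from 109 ± 27.3 to 145 ± 59.3 CPM (camera adjusted p = 0.000215, adjusted p = 0.596 with an estimated correlation). NF-kB target and feedback genes rose by a median log2 of 0.10 (0.000475, adjusted p = 0.596 with an estimated correlation). edgeR called 0 genes in Nlrp3+/+ macrophages (1634 at an unadjusted p below 0.05, DESeq2 40) and 0 over both genotypes (1081, DESeq2 38), and leaving out any 1 library left both at 0. No pooled comparison of S100B was simulated. In counts simulated on the genotype comparison of 12 against 12 macrophage libraries edgeR recovered 94% of 2-fold changes.

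In neutrophils S100B was followed by no called change of a cytokine. Il1b in Nlrp3+/+ decidual neutrophils stood at 17942 ± 1503 CPM after S100B and 16244 ± 2316 CPM after PBS (n = 2 each, log2 0.14 ± 0.20, edgeR). In uterine neutrophils it stood at 15858 ± 241 and 13279 ± 740 CPM (n = 2 each, log2 0.26 ± 0.20). Egr1, an immediate early transcription factor, stood at 5788 ± 466 against 3451 ± 20.4 CPM in the uterus. The immediate early and dissociation stress list rose there (camera adjusted p = 0.0437, adjusted p = 0.684 with an estimated correlation). Erythroid markers rose in decidual neutrophils (camera adjusted p = 0.00157, adjusted p = 0.929 with an estimated correlation) and fell in uterine neutrophils (0.000123, adjusted p = 0.684 with an estimated correlation). The processed pseudogene Gm28900 (chromosome 1, 56451407 to 56451562) held 58.1 ± 32.7 CPM after PBS and 0 after S100B in the uterus, the only gene called there (edgeR adjusted p = 0.0138). It lost its call without PBS replicate 1 (0.0657) or S100B replicates 5 (0.232) and 6 (0.110), and a fit of uterine neutrophils alone called 0 genes. In decidua edgeR called 0 genes (243 at an unadjusted p below 0.05, DESeq2 545), or 1 without PBS replicate 1. DESeq2 called 432 in the uterus. In counts simulated on the decidual comparison 461 of its 481 calls were of unchanged genes, while edgeR recovered 0% of even 4-fold changes, and no comparison within the uterus was simulated. The erythroid call was lost in decidua without PBS replicates 1 (adjusted p = 0.597) or 2 (0.0614) and reversed without S100B replicate 5 (0.247). In uterus it was lost without PBS replicate 2 (0.198) or S100B replicate 6 (0.364). The immediate early call was lost without PBS replicate 2 (0.198) or S100B replicates 5 (0.144) and 6 (0.169).

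Over both tissues the Nlrp3+/+ neutrophils carried slightly more neutrophil marker transcript after S100B, 86692 ± 40041 against 74583 ± 28067 CPM (n = 4 each, median log2 0.18, camera adjusted p = 0.0310, adjusted p = 0.853 with an estimated correlation). Gm28900 was again the only gene edgeR called (adjusted p = 0.0280). Leaving out any 1 of the 8 libraries took its call away (adjusted p = 0.0575 to 0.483), although without PBS decidual replicate 1 or S100B decidual replicate 5 another gene took its place. Over both genotypes as well, edgeR called 0 genes (692 at an unadjusted p below 0.05, DESeq2 729) and camera passed 0 of 32 lists. Il1b stood there at 15420 ± 3118 and 16048 ± 3064 CPM (n = 8 each, log2 -0.07 ± 0.10). Without Nlrp3-/- PBS uterine replicate 8 that count of 0 became 234, and without Nlrp3+/+ PBS decidual replicate 1 or Nlrp3-/- PBS decidual replicate 8 it became 1. The neutrophil list lost its call without PBS decidual replicate 1 (0.165), PBS uterine replicate 2 (0.0539) or S100B decidual replicate 6 (0.128).

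In macrophages without NLRP3 several inflammatory lists rose after S100B, none of them with an estimated correlation. In Nlrp3-/- uterine macrophages Il1b stood at 1060 ± 202 CPM after S100B and 769 ± 186 CPM after PBS (n = 3 each, log2 0.46 ± 0.21, edgeR). Il6, a cytokine that drives fever and the acute phase, stood at 27.9 ± 10.05 and 13.2 ± 3.12 CPM (log2 1.08 ± 0.44). Nfkbia, the inhibitor that NF-kB itself induces, stood at 1044 ± 185 and 758 ± 142 CPM (log2 0.46 ± 0.18). The NF-kB target and feedback list rose there (21 of 25 higher, camera adjusted p = 3.46e-09, adjusted p = 0.120 with an estimated correlation), as did the inflammatory cytokine list (1.25e-05, adjusted p = 0.116 with an estimated correlation). The alarmin and S100 sensing list rose (0.0171, adjusted p = 0.170 with an estimated correlation), led by Cd14, a co-receptor of TLR4, at 1049 ± 103 against 735 ± 176 CPM. In Nlrp3-/- decidual macrophages Ccl22, a chemokine for regulatory T cells, stood at 15.1 ± 4.36 against 6.78 ± 3.30 CPM and the cytokine list rose (0.00522, adjusted p = 0.435 with an estimated correlation). Il1b stood there at 1025 ± 69.7 against 1000 ± 174 CPM (log2 0.04 ± 0.21). The homeostatic list rose in decidua, with Mrc1, the mannose receptor, at 179 ± 15.0 against 120 ± 25.7 CPM (camera adjusted p = 1.89e-09, adjusted p = 0.435 with an estimated correlation). All 34 cell cycle genes were lower there (1.55e-12, adjusted p = 0.435 with an estimated correlation). edgeR called 0 genes in decidua (382 at an unadjusted p below 0.05, DESeq2 22) and 0 in uterus (298, DESeq2 32), counts that no single library changed. The cytokine list lost its call in uterus without S100B replicate 16 (0.0880) and in decidua without PBS replicate 12 (0.0661) or S100B replicate 17 (0.115). The alarmin list lost it without PBS replicate 12 (0.141) or S100B replicate 17 (0.0872). Markers of other cells rose beside these lists. Eosinophil or mast cell markers rose in uterus (camera adjusted p = 1.17e-05, adjusted p = 0.0641 with an estimated correlation, 752 ± 159 against 602 ± 166 CPM). Erythroid markers rose in decidua (0.00163, adjusted p = 0.438 with an estimated correlation, lost without PBS replicate 12 at 0.228).

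Nlrp3-/- uterine neutrophils held more transcript of macrophages after S100B. C1qa, a complement component made by macrophages, stood at 2782 ± 297 CPM after S100B and 1535 ± 93.3 CPM after PBS (n = 2 each, log2 0.86 ± 0.29). Cd68, a lysosomal protein of macrophages, stood at 1376 ± 488 and 631 ± 86.7 CPM (log2 1.12 ± 0.29, adjusted p = 0.0377 over the list alone). The macrophage marker list rose (camera adjusted p = 0.0127, adjusted p = 0.748 with an estimated correlation) from 12107 ± 2334 to 20953 ± 1194 CPM, a call lost without S100B replicate 11 (0.0990). In decidua the MHC class II presentation list rose (camera adjusted p = 0.00101, adjusted p = 0.794 with an estimated correlation), with H2-Ab1, a chain of the MHC class II molecule, at 3290 ± 674 against 1526 ± 1086 CPM. It lost its call without PBS replicate 7 (0.320) or S100B replicate 11 (0.204). Neutrophil markers stood lower in the same libraries, at 75150 ± 2515 against 132610 ± 43759 CPM, although the list did not pass (camera adjusted p = 0.323). Among them the stefin Stfa2l1, stood at 293 ± 97.2 against 1052 ± 495 CPM (log2 -1.84 ± 0.43, adjusted p = 0.0174 over the list alone). Il1b stood at 16684 ± 2198 against 19536 ± 3478 CPM in decidua (log2 -0.23 ± 0.20, edgeR). In uterus it stood at 11197 ± 2991 against 15131 ± 2505 CPM (log2 -0.43 ± 0.20, adjusted p = 0.659). edgeR called 0 genes in decidua (347 at an unadjusted p below 0.05, DESeq2 669) and 0 in uterus (962, DESeq2 1504). Those counts became 5 without PBS decidual replicate 8 and 443 without PBS uterine replicate 8, which leaves a single library on the PBS side whose spread is then taken from the other groups.

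Whether NLRP3 altered the response to S100B was tested as the difference between the 2 genotypes' responses. Il1b differed by log2 0.43 ± 0.29 in uterine macrophages (edgeR adjusted p = 0.661), by 0.28 ± 0.29 in decidual macrophages and by -0.69 ± 0.29 in uterine neutrophils (adjusted p = 0.824). In Nlrp3-/- uterine macrophages 26 of 34 cell cycle genes were lower after S100B (camera adjusted p = 0.000596, adjusted p = 0.521 with an estimated correlation), a call that 2 of 6 leave-one-out fits lost (up to 0.164). Against the rise of these genes in Nlrp3+/+, Top2a differed by log2 -1.34 ± 0.37 (adjusted p = 0.0352 over the list alone). Prc1, which bundles microtubules in dividing cells, differed by -0.95 ± 0.27 (0.0352). The cell cycle list differed (camera adjusted p = 1.20e-06, adjusted p = 0.778 with an estimated correlation). The glycolysis and hypoxia list differed in the other direction (1.71e-05, adjusted p = 0.778 with an estimated correlation). The NF-kB, inflammatory cytokine and alarmin lists, which rose in Nlrp3-/- and not in Nlrp3+/+ uterine macrophages, were not shown to differ between the genotypes there (camera adjusted p = 0.0783, 0.0943 and 0.0622). In decidual macrophages the type I interferon list differed (median log2 -0.36, camera adjusted p = 0.000866, adjusted p = 0.958 with an estimated correlation), a call lost without Nlrp3+/+ S100B replicate 7 (0.0707). edgeR called 0 genes in decidual macrophages (372 at an unadjusted p below 0.05, DESeq2 18) and 0 in uterine macrophages (1209, DESeq2 36; 1 without Nlrp3+/+ S100B replicate 8). In decidual neutrophils it called 0 (472, DESeq2 494; 1 without Nlrp3+/+ PBS replicate 1 or Nlrp3-/- PBS replicate 8). In uterine neutrophils it called only Gm28900 (adjusted p = 0.0249, 861 genes at an unadjusted p below 0.05, DESeq2 897). The Gm28900 call was kept in 1 of 8 leave-one-out fits, without Nlrp3-/- PBS replicate 8 (0.00379), where 345 genes were called. A fit of uterine neutrophils alone called 0 genes. The call was otherwise lost with adjusted p from 0.0512 without Nlrp3+/+ PBS replicate 2 to 0.246 without Nlrp3+/+ S100B replicate 5. The MHC class II list differed in decidual neutrophils (camera adjusted p = 0.00150, adjusted p = 0.605 with an estimated correlation). It was lost without Nlrp3+/+ PBS replicate 1 (0.0803), Nlrp3-/- PBS replicate 7 (0.124) or Nlrp3-/- S100B replicate 11 (0.0765).

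Under PBS, uterine macrophages without NLRP3 held less transcript of interferon-stimulated genes, of glycolytic enzymes and of lipid handling genes than those with it. Irf7, the transcription factor that amplifies interferon production, stood at 35.7 ± 2.32 CPM in Nlrp3-/- and 128 ± 106 CPM in Nlrp3+/+ (n = 3 each, log2 -1.85 ± 0.39, adjusted p = 0.00265 over the list alone). Oas1a, a sensor of double-stranded RNA, stood at 81.4 ± 4.62 and 148 ± 61.5 CPM (log2 -0.87 ± 0.21, 0.00641). Eno1, the glycolytic enolase, stood at 618 ± 29.3 and 1035 ± 173 CPM (log2 -0.74 ± 0.18, 0.00720). Plin2, which coats lipid droplets, stood at 344 ± 70.7 and 729 ± 266 CPM (log2 -1.08 ± 0.24, 0.00593). Gbp2, a guanylate-binding protein that interferon gamma induces, stood at 10.02 ± 0.560 and 19.6 ± 4.78 CPM (log2 -0.97 ± 0.27). Ptgs2, the prostaglandin synthase of labour, stood at 6.33 ± 1.45 and 15.9 ± 5.34 CPM (log2 -1.33 ± 0.41). The glycolysis and hypoxia list (camera adjusted p = 2.16e-16, median log2 -0.62), the interferon gamma list (4.96e-09), the alarmin list (0.000530) and the contraction and labour-associated list (0.000613) fell, each with an adjusted p = 0.0400 with an estimated correlation. The lysosome and lipid handling list fell too (8.79e-13, adjusted p = 0.0432 with an estimated correlation), and all 40 type I interferon genes were lower (1.11e-21, adjusted p = 0.118 with an estimated correlation). With Nlrp3 taken out of the inflammasome list, adjusted with these, the lysosome list missed the threshold with an estimated correlation (0.0504). The 4 before it passed (0.0480). Nlrp3+/+ replicate 3 carried most of the fall of the interferon list. Without it the median log2 went from -0.899 to -0.177 (camera adjusted p = 0.000117, 0.348 with an estimated correlation). Without it the glycolysis list reversed between tissues in Nlrp3+/+ PBS macrophages (camera adjusted p = 0.189). Monocyte markers were lower, 1307 ± 209 against 1655 ± 545 CPM (camera adjusted p = 0.000386, 0.129 with an estimated correlation). Neutrophil markers stood at 132 ± 37.2 against 437 ± 276 CPM (1.00e-06, 0.0586 with an estimated correlation). edgeR called 2 genes of 17154 (1558 at an unadjusted p below 0.05, DESeq2 166), Nlrp3 and Hist3h2a, a histone gene at 9.52 ± 0.329 against 26.1 ± 2.67 CPM (adjusted p = 0.00193). Without Nlrp3+/+ replicate 1 it called 17, Irf7 (0.0259) among them, and a fit of uterine macrophages alone called 1.

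**Figure D2:**
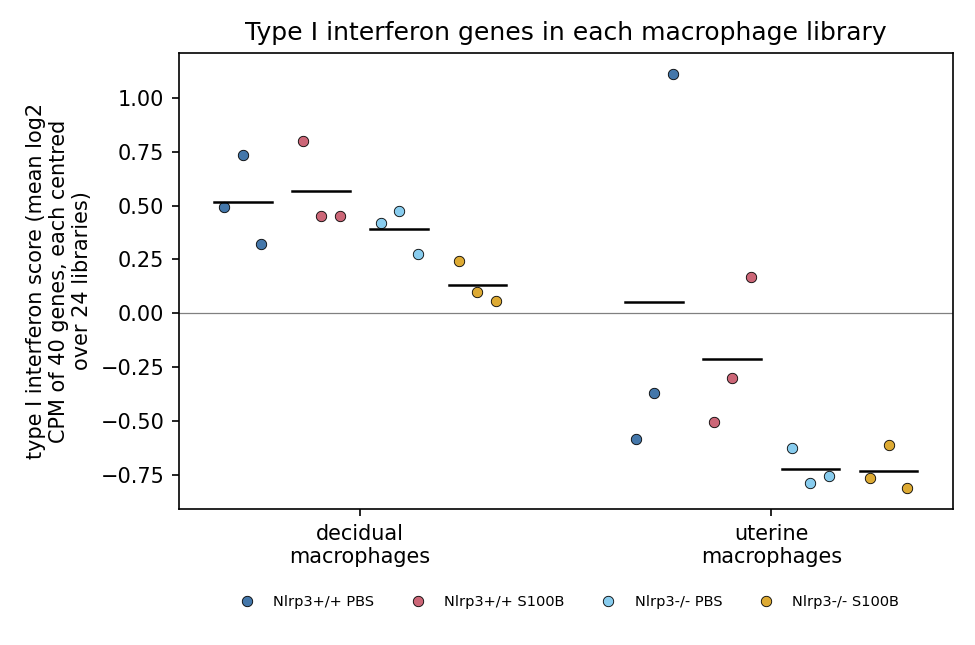
Type I interferon score of each macrophage library, the mean log2 CPM of 40 genes after each was centred over 24 libraries, by tissue, genotype and treatment. Uterine Nlrp3+/+ PBS libraries scored -0.58, -0.37 and 1.11 and uterine Nlrp3-/- PBS libraries -0.62, -0.79 and -0.75.

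After S100B interferon and lipid genes were again lower as lists in Nlrp3-/- uterine macrophages, but not with an estimated correlation. Isg15, a ubiquitin-like product of interferon signalling, stood at 75.2 ± 7.58 CPM in Nlrp3-/- and 176 ± 100 CPM in Nlrp3+/+ (n = 3 each, log2 -1.23 ± 0.38, adjusted p = 0.0401 over the list alone). Bst2, the antiviral tetherin, stood at 452 ± 37.9 and 724 ± 165 CPM (log2 -0.68 ± 0.20, 0.0401). Plin2 stood at 307 ± 9.06 and 594 ± 140 CPM (log2 -0.95 ± 0.24, 0.0270). Cxcr4, the receptor that holds leukocytes in bone marrow, stood at 18.3 ± 4.84 and 37.8 ± 12.7 CPM (log2 -1.05 ± 0.25, 0.0127). Timd4, which binds phosphatidylserine on dying cells and marks long-lived resident macrophages, rose from 1.49 ± 1.53 to 24.6 ± 7.10 CPM (log2 4.04 ± 0.61, edgeR adjusted p = 0.0126). Type I interferon (camera adjusted p = 1.36e-11), lysosome and lipid handling (5.61e-05), aged or tissue-activated neutrophil genes (0.000178) and cell cycle genes (2.19e-08) fell as lists, each with an adjusted p = 0.456 with an estimated correlation. Monocyte markers fell beside them, 1487 ± 132 against 1772 ± 337 CPM (0.0179, adjusted p = 0.456 with an estimated correlation), a call that 4 of the 6 leave-one-out fits lost. edgeR called 4 genes (1508 at an unadjusted p below 0.05, DESeq2 91), Nlrp3, Hist3h2a (adjusted p = 0.00203), Timd4 and the scarcely expressed Gm29487 at 1.71 ± 1.19 CPM against 0 (0.0399). Timd4 lost its call without Nlrp3+/+ replicate 7 (0.120) or Nlrp3-/- replicate 16 (0.0509). Gm29487 lost it in 5 of 6 leave-one-out fits (up to 0.430 without Nlrp3+/+ replicate 9, kept only without Nlrp3-/- replicate 16). The count ran from 2 without Nlrp3+/+ replicate 7 to 11 without Nlrp3+/+ replicate 8, and a fit of uterine macrophages alone called 1.

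Decidual macrophages without NLRP3 had fewer transcripts of dividing cells under both treatments. Under PBS, Bub1, a kinase of the spindle checkpoint, stood at 2.46 ± 0.570 against 5.08 ± 0.915 CPM (n = 3 each, log2 -1.05 ± 0.35). After S100B Prc1 stood at 7.75 ± 1.66 against 13.3 ± 1.25 CPM (log2 -0.78 ± 0.19, adjusted p = 0.0201 over the list alone). The cell cycle list fell under PBS (33 of 34 lower, camera adjusted p = 2.59e-10, adjusted p = 0.266 with an estimated correlation) and after S100B (32 of 34 lower, 3.11e-12, adjusted p = 0.346 with an estimated correlation). Il1a, an interleukin 1 that acts without cleavage by caspase 1, stood at 111 ± 11.2 against 248 ± 80.7 CPM under PBS (log2 -1.16 ± 0.34, not called). The inflammasome and pyroptosis list fell there with Nlrp3 as a member (camera adjusted p = 0.00114, adjusted p = 0.197 with an estimated correlation) and did not pass without it (0.585). After S100B Oas1a stood at 120 ± 8.60 against 160 ± 38.1 CPM and the type I interferon list fell (1.06e-09, adjusted p = 0.420 with an estimated correlation). Monocyte markers fell beside it, 3353 ± 401 against 3829 ± 339 CPM (camera adjusted p = 0.0494, adjusted p = 0.477 with an estimated correlation). That call was lost in 4 of 6 leave-one-out fits (up to 0.249) and with Nlrp3 taken out of the inflammasome list (0.0527). Il12b, a subunit of interleukins 12 and 23, stood at 2.69 ± 1.85 against 0.490 ± 0.0763 CPM after S100B (adjusted p = 0.00491 over the list alone). The inflammatory cytokine list rose there (0.00361, adjusted p = 0.346 with an estimated correlation). Trophoblast markers rose under PBS, with Tpbpa at 24.5 ± 20.2 against 2.69 ± 2.71 CPM (camera adjusted p = 8.54e-06, adjusted p = 0.197 with an estimated correlation). B cell markers rose after S100B (0.00402, adjusted p = 0.346 with an estimated correlation). edgeR called Nlrp3 and Hist3h2a only, under PBS (511 genes at an unadjusted p below 0.05, DESeq2 42) and after S100B (1009, DESeq2 57). Hist3h2a stood at 11.6 ± 2.48 against 27.7 ± 3.55 CPM under PBS (adjusted p = 0.0146) and 11.8 ± 0.258 against 28.8 ± 2.42 CPM after S100B (0.0104). Its call was lost under PBS without Nlrp3+/+ replicates 1 (0.161) and 2 (0.0538) or Nlrp3-/- replicates 11 (0.0779) and 12 (0.183). After S100B it was lost without Nlrp3+/+ replicate 7 (0.0729) or Nlrp3-/- replicates 16 (0.1003), 17 (0.120) and 18 (0.113), each leaving 1 called gene. In a fit of decidual macrophages alone Hist3h2a lost its call under PBS (0.0940) and after S100B (0.0723), where a gene higher in Nlrp3-/- took its place.

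Over all 4 macrophage groups of each genotype edgeR called 68 genes, 20 higher and 48 lower without NLRP3 (2232 at an unadjusted p below 0.05, DESeq2 433, n = 12 each). Without the expression filter it called 34, 11 higher and 23 lower. With the replicate number as a random effect in voom 37 were called, 18 higher and 19 lower, so the excess of lower genes depends on the method. Timd4 rose from 1.92 ± 0.878 to 21.5 ± 7.24 CPM (log2 3.49 ± 0.30, adjusted p = 1.73e-06). Cd209c, a lectin receptor, rose from 14.7 ± 4.45 to 25.2 ± 3.68 CPM (log2 0.79 ± 0.14, adjusted p = 0.0151). Plin2 fell from 731 ± 181 to 415 ± 122 CPM (log2 -0.85 ± 0.12, adjusted p = 0.00183). Hilpda, a lipid droplet protein induced by low oxygen, fell from 118 ± 38.1 to 67.1 ± 18.8 CPM (log2 -0.79 ± 0.13, adjusted p = 0.00917). Angptl4, an inhibitor of lipoprotein lipase, fell from 14.1 ± 5.07 to 5.32 ± 3.13 CPM (log2 -1.46 ± 0.26, adjusted p = 0.0166). Chil3, a lectin of alternatively activated macrophages, fell from 484 ± 359 to 194 ± 163 CPM (log2 -1.56 ± 0.26, adjusted p = 0.00718). Irf7 fell from 144 ± 79.6 to 90.5 ± 60.2 CPM (log2 -0.88 ± 0.19, adjusted p = 0.0471), but lost its call in 20 of 24 leave-one-out fits (adjusted p up to 0.0962). All 40 type I interferon genes were lower (camera adjusted p = 2.36e-26, adjusted p = 0.101 with an estimated correlation). So were 29 of 31 lysosome and lipid handling genes (7.76e-12, adjusted p = 0.0571 with an estimated correlation), and Apoe, a carrier of lipid, stood at 15389 ± 2344 against 19856 ± 3100 CPM. The complement and efferocytosis list fell (0.00193, adjusted p = 0.120 with an estimated correlation) and so did the endoplasmic reticulum stress list (0.00391, adjusted p = 0.268 with an estimated correlation). The inflammasome list fell with Nlrp3 itself as a member (3.73e-07, adjusted p = 0.0392 with an estimated correlation). Without Nlrp3 it did not pass (camera adjusted p = 0.240, adjusted p = 0.490 with an estimated correlation, 11 of 20 lower), in a test added after the data had been seen. Il1b stood at 964 ± 185 against 1055 ± 226 CPM (log2 -0.13 ± 0.10, adjusted p = 0.645). Casp1, Pycard and Gsdmd, the partners and target of NLRP3, had adjusted p values of 0.768, 0.403 and 0.490. Neutrophil markers were lower without NLRP3 (174 ± 40.4 against 322 ± 145 CPM, camera adjusted p = 2.83e-08, adjusted p = 0.0519 with an estimated correlation). The number called moved by more than 1.5-fold in 20 of 24 leave-one-out fits, from 25 without Nlrp3-/- PBS uterine replicate 10 to 173 without Nlrp3+/+ S100B decidual replicate 8. The exceptions were Nlrp3+/+ PBS decidual replicate 3, PBS uterine replicate 2 and S100B uterine replicates 7 and 8.

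Genes beside Nlrp3 on chromosome 11 were called more often than genes elsewhere. Besides Nlrp3, 10 of the 260 tested genes within 10 Mb of it were called, against 57 of 16893 elsewhere. The flanking genes as a list did not move in either direction (camera adjusted p = 0.352). Hist3h2a fell from 26.5 ± 4.12 to 10.4 ± 1.84 CPM (log2 -1.36 ± 0.09, edgeR adjusted p = 6.12e-08, n = 12 each). Zfp672, a zinc finger gene, fell from 14.7 ± 1.99 to 9.46 ± 1.65 CPM (adjusted p = 0.000233). Trim11, a ubiquitin ligase, fell from 20.5 ± 3.14 to 13.2 ± 2.13 CPM (adjusted p = 0.00581). Anxa6, a membrane-binding annexin, rose from 66.9 ± 13.4 to 103 ± 17.4 CPM (adjusted p = 0.00720). Timd4 lies on the same chromosome, 12.7 Mb from Nlrp3.

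**Figure D3:**
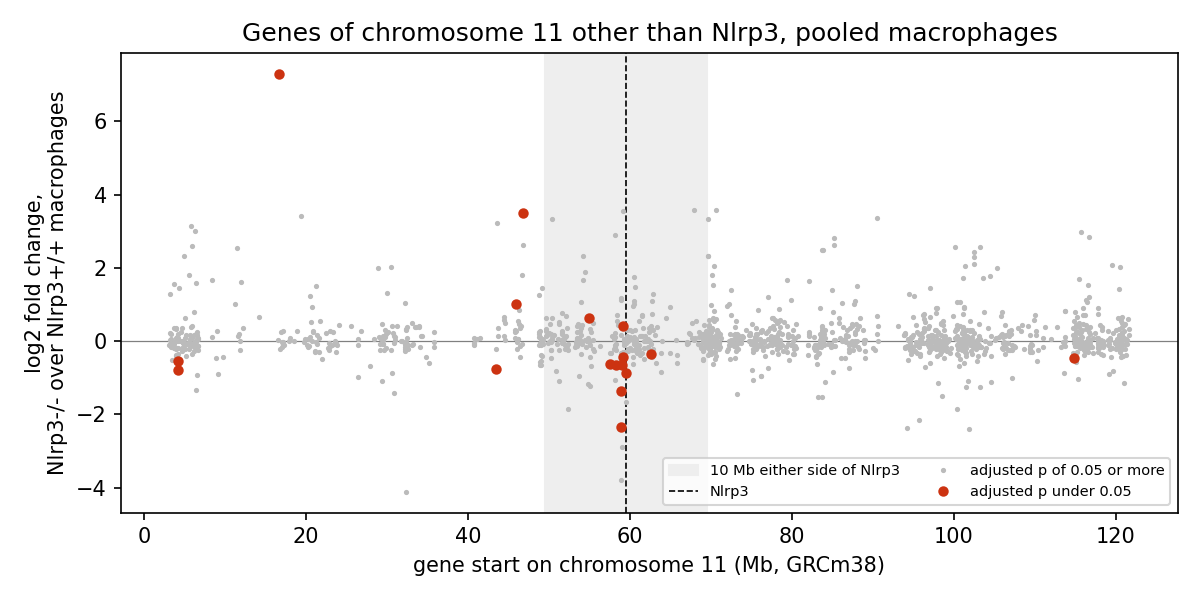
Log2 fold change of Nlrp3-/- over Nlrp3+/+ macrophages for each tested gene of chromosome 11 against its start in Mb (GRCm38), without Nlrp3 itself. Red genes have an adjusted p under 0.05 and the grey band spans 10 Mb either side of Nlrp3.

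In neutrophils the genotypes differed in macrophage and interferon transcripts. After S100B C1qa stood at 1274 ± 54.9 CPM in Nlrp3-/- and 527 ± 6.94 CPM in Nlrp3+/+ decidual neutrophils (n = 2 each, log2 1.27 ± 0.30, adjusted p = 0.0169 over the list alone). In uterine neutrophils it stood at 2782 ± 297 and 1136 ± 83.9 CPM (log2 1.29 ± 0.30, 0.0152). The macrophage marker list rose in both (camera adjusted p = 0.00138, adjusted p = 0.423 with an estimated correlation, and 0.000481, adjusted p = 0.640 with an estimated correlation). Retnlg, a resistin-like protein of neutrophils, stood at 2013 ± 113 against 5538 ± 1595 CPM in decidua. Under PBS Isg15 stood at 185 ± 88.9 against 562 ± 317 CPM in uterine neutrophils, where the type I interferon list fell (0.0385, adjusted p = 0.930 with an estimated correlation). Over all groups Oasl2, an interferon-induced synthetase-like protein, stood at 394 ± 124 against 641 ± 166 CPM (n = 8 each). Of 40 type I interferon genes 35 were lower (camera adjusted p = 0.00181, adjusted p = 0.537 with an estimated correlation). Stroma and fibroblast markers were higher in Nlrp3-/- over all groups (888 ± 1435 against 87.4 ± 45.04 CPM, 0.00181, adjusted p = 0.410 with an estimated correlation). Without the highest library, PBS uterine replicate 7, the Nlrp3-/- mean was 478 ± 911 CPM, and 4 of 16 leave-one-out fits lost the list's call (up to 0.1033). edgeR called Nlrp3 in each of the 4 comparisons and over all groups, and besides it only Gm28900 in uterine neutrophils after S100B, at 52.6 ± 8.55 CPM against 0 (adjusted p = 0.01002). The genes at an unadjusted p below 0.05 and the DESeq2 calls were 277 and 536 (PBS decidua), 304 and 681 (S100B decidua), 663 and 1054 (PBS uterus), 672 and 913 (S100B uterus) and 855 and 934 (over all groups).

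Leaving out 1 library ended many of those neutrophil calls. The fall of Nlrp3 itself rested on no single library, since each Nlrp3+/+ neutrophil library held at least 6429 reads of it and each Nlrp3-/- library at most 8. Even so Nlrp3 lost its call in decidual neutrophils without Nlrp3-/- replicates 7 (edgeR adjusted p = 0.623) and 8 (0.168) under PBS and 11 (0.548) and 12 (0.269) after S100B. In uterine neutrophils it lost it under PBS without Nlrp3+/+ replicates 1 (0.181) and 2 (0.1247) or Nlrp3-/- replicate 7 (0.508), and after S100B without Nlrp3+/+ replicate 5 (0.0785) or Nlrp3-/- replicates 11 (0.268) and 12 (0.275). Gm28900 lost it after S100B without any 1 of the 4 libraries (0.0510 to 0.1246). Fits of 1 tissue's neutrophils alone called 0 genes in all 4 comparisons, Nlrp3 included. The count of calls became 407 without Nlrp3-/- PBS uterine replicate 8, 7 without Nlrp3+/+ PBS decidual replicate 1, 289 over all groups without that Nlrp3-/- replicate 8, 3 without Nlrp3+/+ PBS decidual replicate 1 and 2 without Nlrp3+/+ S100B decidual replicates 5 or 6. Without Nlrp3+/+ S100B replicate 6 the macrophage list lost its call in decidua (0.141) and in uterus (0.116). The type I interferon list lost it under PBS without Nlrp3+/+ replicate 2 (0.955) or Nlrp3-/- replicate 8 (0.338), and over all groups without Nlrp3+/+ PBS uterine replicate 2 (0.0505).

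Over all macrophages, more genes were called between decidua and uterus than between genotypes or treatments. Ace, the angiotensin-converting enzyme of patrolling monocytes, rose from 2.17 ± 1.05 CPM in uterus to 21.3 ± 5.82 CPM in decidua over all groups (n = 12 each, log2 3.28 ± 0.23, edgeR adjusted p = 3.15e-08). Plac8, abundant in Ly6C-high monocytes, rose from 227 ± 190 to 1242 ± 307 CPM (log2 2.56 ± 0.29, 1.21e-05). Irf7 rose from 68.0 ± 60.0 to 167 ± 51.2 CPM (log2 1.47 ± 0.19, 6.88e-05). Stat1, a transcription factor of interferon signalling, rose from 197 ± 64.0 to 328 ± 59.5 CPM (log2 0.75 ± 0.13, 0.00102). Tnf fell from 233 ± 35.3 CPM in uterus to 128 ± 28.8 CPM in decidua (log2 -0.87 ± 0.11, 4.44e-05). Ccl4, a chemokine for monocytes and T cells, fell from 1209 ± 442 to 597 ± 196 CPM (log2 -0.997 ± 0.17, 0.00127), and Cxcl2 from 1399 ± 226 to 1044 ± 137 CPM (log2 -0.42 ± 0.08, 0.00291). Gsdmd rose from 54.5 ± 10.6 to 70.7 ± 14.1 CPM (log2 0.39 ± 0.10, 0.0358, call lost in 14 of 24 leave-one-out fits). edgeR called 855 genes, 570 higher and 285 lower in decidua (2989 at an unadjusted p below 0.05, DESeq2 1403). Leave-one-out fits called 621 to 1029. Monocyte markers (camera adjusted p = 5.82e-38, 3.79e-05 with an estimated correlation), type I interferon (5.93e-37, 0.0408), interferon gamma (4.74e-14, 0.0105) and neutrophil granule genes (2.35e-10, 0.0166) rose as lists. The granule list is not specific to neutrophils, at 22296 CPM in decidual macrophages and 18079 in decidual neutrophils. Neutrophil markers stood at 234 against 261 CPM. Cell cycle genes fell (6.58e-14, 0.0607), with Mki67 at 8.12 ± 1.60 against 12.2 ± 2.73 CPM. Inflammatory cytokines fell too (0.00109, 0.0962).

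Granzyme transcripts set the decidual macrophage libraries apart from the uterine ones. Gzmd and Gzmg, serine proteases of decidual killer cells, stood at 327 ± 136 and 381 ± 156 CPM in decidua against 0.108 ± 0.185 and 0.159 ± 0.347 CPM in uterus (n = 12 each, edgeR adjusted p = 1.49e-10 and 1.46e-08). Salmon divides reads among near-identical copies, so the share of each granzyme, and likewise of each prolactin family member, haemoglobin and histone gene, is uncertain. NK cell markers rose to 1487 ± 586 from 61.5 ± 14.6 CPM (camera adjusted p = 7.62e-25, adjusted p = 0.00487 with an estimated correlation). Most of that sum was Gzmc to Gzmg (1391.5 against 3.68 CPM), while the other 11 markers summed to 95.7 against 57.8 CPM, 3 of them called. Trophoblast markers rose to 72.5 ± 87.0 from 1.29 ± 0.811 CPM (3.08e-06, 0.0458), with Tpbpa at 29.9 ± 40.2 against 0.0450 ± 0.0690 CPM. Erythroid markers fell to 1392 ± 974.9 from 4043 ± 2542 CPM (3.08e-06, adjusted p = 0.0607 with an estimated correlation) and uterine epithelium markers to 60.6 ± 26.7 from 113 ± 39.99 CPM (5.84e-05, 0.0425). Smooth muscle markers (17.2 ± 4.16 against 12.3 ± 2.27 CPM, 0.00359) and endothelial markers (21.01 ± 5.38 against 16.6 ± 3.04 CPM, 0.0118) rose, both with an adjusted p = 0.0962 with an estimated correlation. Dendritic cell markers stood at 159 ± 45.6 against 156 ± 43.4 CPM (0.0697). Among PBS-treated Nlrp3+/+ libraries alone edgeR called 11 genes, all higher in decidua (588 at an unadjusted p below 0.05, DESeq2 83), among them Gzmd (adjusted p = 3.25e-05) and Ace (0.00512, n = 3 each). There Ccl2, a chemokine for monocytes, stood at 352 ± 44.7 against 731 ± 169 CPM and the inflammatory cytokines fell (camera adjusted p = 2.46e-07, adjusted p = 0.0243 with an estimated correlation). T cell markers fell (0.0268, adjusted p = 0.361 with an estimated correlation, but reversed at 0.976 without uterine replicate 2). That count became 7 without decidual replicates 1 or 3, 5 without uterine replicates 1 or 2 and 31 without uterine replicate 3, and Ace lost its call without uterine replicates 1 (0.0950) or 2 (0.0804). A fit of those 2 groups alone called 2 genes.

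**Figure D4:**
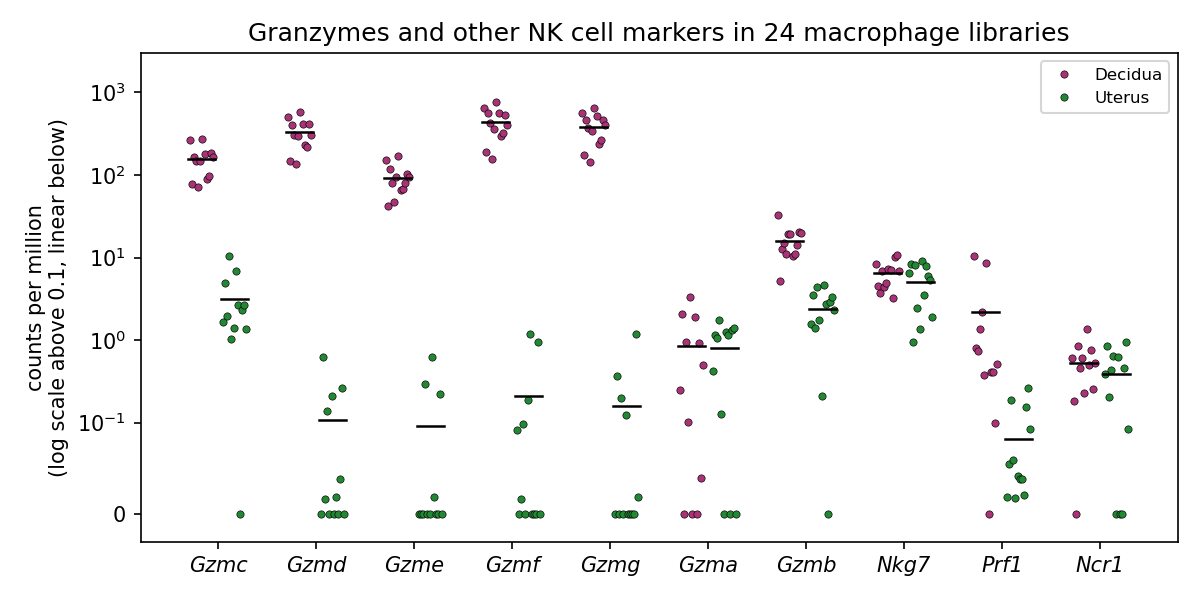
Granzymes and other NK cell markers in CPM in the 24 macrophage libraries, decidua against uterus. Gzmd averages 327 CPM in decidua and 0.108 in uterus, and the bars are means of 12 libraries.

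Decidual neutrophils carried more neutrophil transcript and less macrophage transcript than uterine ones. S100a8, a calcium-binding protein of neutrophil cytosol, stood at 38178 ± 17675 CPM in decidua and 15527 ± 3086 CPM in uterus (n = 8 each, log2 1.24 ± 0.20, edgeR adjusted p = 0.0603). Retnlg rose from 1263 ± 600 to 3574 ± 1555 CPM (log2 1.52 ± 0.18, adjusted p = 0.0249). C1qa fell to 829 ± 344 from 1725 ± 684 CPM (log2 -1.05 ± 0.15, adjusted p = 0.0471). Spp1, the matrix protein osteopontin, fell to 420 ± 103 from 1530 ± 840 CPM (log2 -1.85 ± 0.26, adjusted p = 0.0471). Ccl3, a chemokine of activated leukocytes, stood at 1384 ± 314 against 2647 ± 538 CPM. The inflammatory cytokines fell as a list (camera adjusted p = 0.00176, adjusted p = 0.0391 with an estimated correlation). Neutrophil markers rose (3.58e-10) and macrophage markers fell (9.34e-11), both with an adjusted p = 0.0391 with an estimated correlation, and the complement list fell (1.68e-06, adjusted p = 0.0182 with an estimated correlation). edgeR called 11 genes over all groups, 5 higher and 6 lower in decidua (1234 at an unadjusted p below 0.05, DESeq2 1233) and 0 in PBS-treated Nlrp3+/+ neutrophils (298, DESeq2 493, n = 2 each; 1 without decidual replicate 1). Leaving out 1 library gave 0 genes in 10 of 16 fits, 6 without Nlrp3+/+ PBS decidual replicate 2, 19 without Nlrp3+/+ S100B decidual replicate 6, 24 without Nlrp3-/- PBS decidual replicate 8 and 319 without Nlrp3-/- PBS uterine replicate 8. Retnlg, C1qa and Spp1 lost their calls in 11, 13 and 14 of the 16 (adjusted p up to 0.144, 0.188 and 0.188). With the replicate number as a random effect in voom 23 genes were called, 18 higher and 5 lower, with 7 of the 11 among them. Retnlg (0.156) and Spp1 (0.275) lost their calls there. Among PBS-treated Nlrp3+/+ neutrophils alone the macrophage markers fell as well (camera adjusted p = 8.25e-05, adjusted p = 0.237 with an estimated correlation), with Ms4a7, a macrophage membrane protein, at 27.2 ± 11.4 against 164 ± 69.4 CPM.

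edgeR called no macrophage gene and 1 neutrophil gene for a different response to S100B in the 2 tissues. In Nlrp3+/+ macrophages Pcna differed between decidua and uterus by log2 -0.61 ± 0.18 and Top2a by -1.28 ± 0.37 (adjusted p = 0.0457 over the list alone). The cell cycle list differed (31 of 34 lower, camera adjusted p = 3.83e-11, adjusted p = 0.822 with an estimated correlation). In macrophages 863 genes had an unadjusted p below 0.05 (DESeq2 called 29). The neutrophil gene was Gm28900 (edgeR adjusted p = 0.0402; 353, DESeq2 324). That call was kept in 1 of 8 leave-one-out fits, without S100B decidual replicate 6 (0.0472), where 2 genes were called. It was lost in the rest, up to 0.704 without PBS decidual replicate 2. It was also lost with the replicate number as a block and in a fit of the compared groups alone, each with 0 genes called. The erythroid list differed in neutrophils (3.21e-07, adjusted p = 0.766 with an estimated correlation), lost without decidual PBS replicate 1 (0.185), decidual S100B replicate 5 (0.379) or uterine S100B replicate 6 (0.333). Il1b differed by log2 -0.28 ± 0.29 in macrophages (edgeR adjusted p = 0.939) and -0.11 ± 0.29 in neutrophils. Across 7103 genes the S100B responses of Nlrp3+/+ decidual and uterine macrophages shared 23 genes at an unadjusted p below 0.05 where 26.8 would by chance, 16 with the same sign. Over all these genes the responses had a Spearman rho of 0.316 and a Pearson r of -0.106. The genotype differences under PBS and after S100B, from separate libraries, shared 75 genes in decidua where chance gives 13.1, all 75 with the same sign. In uterus they shared 126 where chance gives 101, with 119 of the same sign. Over all 7103 genes these differences had a Spearman rho of 0.513 in decidua and -0.0247 in uterus (Pearson r 0.294 and 0.151).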

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

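Some tests below were chosen after the results they measure were seen, namely those of replicate 3, of genotype in the other groups, of the chromosome segment and of NK cell RNA. Those of monocyte RNA, of expression level and of trophoblast RNA were set before their results were seen.

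Type I interferon genes were lower in Nlrp3-/- than in Nlrp3+/+ uterine macrophages under PBS (median log2 -0.899, typical standard error of a gene 0.349). Without Nlrp3+/+ replicate 3, scored 1.11 against -0.58 and -0.37, 28 of the 40 genes were lower. The median was then -0.177 (camera adjusted p = 0.000117, 0.348 with an estimated correlation). With a monocyte score as a covariate it was -0.219 (0.00143, 0.585 with an estimated correlation). Each left less than 0.5 of the fall while the list still passed, so neither that library nor monocyte RNA can be told from an effect of NLRP3 in these libraries alone. In the other 3 pairs of macrophage groups the score was lower in Nlrp3-/- each time (mean difference -0.360, exact permutation p = 0.00125 over 8000 assignments). That p takes the pairs as independent, and is too small if libraries of 1 number share a dam. Monocyte markers also fell in 2 of these pairs (camera adjusted p = 0.0179 and 0.0494, S100B uterus and S100B decidua) and no monocyte covariate was used. The test allows a genotype effect but cannot separate NLRP3 from monocyte RNA or anything else that differs between the 2 mouse lines.

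Genes called between genotypes lay near Nlrp3 more often than elsewhere, 3.85% against 0.337% (odds ratio 11.8, 95% interval 5.31 to 23.7, Fisher's exact p = 6.25e-08). Among genes with an average log2 CPM of at least 3 the odds ratio was 11.1 (4.43 to 24.7, Fisher's exact p = 2.26e-06), so higher expression near Nlrp3 is excluded as the reason. The excess is consistent with a chromosome 11 segment of other strain origin carried with the Nlrp3- allele. In neutrophils 8 of 9 such genes moved the same way, but so did 39 of 53 genes called elsewhere, so that agreement adds little. Deposited counts hold no strain variants, so the segment itself was not seen, and the way the allele was made is not in the labels. Hist3h2a may likewise reflect linked sequence, not NLRP3 activity. Timd4, Thg1l and Pttg1, called 12.7 to 16.1 Mb away, counted as elsewhere, so their linkage stays open.

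Granzymes C to G were higher in decidual than in uterine macrophages, by a mean log2 of 10.6 over Gzmc, Gzmd, Gzme, Gzmf and Gzmg. The other 11 NK cell markers rose by a mean log2 of 1.04 (95% interval over genes 0.132 to 1.94), 3 of them called (Gzmb, Prf1 and Cd244a). The bound set to exclude NK cell RNA was an interval below 0.5 of the granzymes' rise, and it was met. It was set wrongly, because Klrk1 (13.5 CPM) and Nkg7 (5.12 CPM) had a uterine level that could hide a small share of NK cell RNA. Of the 6 markers under 1 CPM in uterus Prf1 was called, and Ncr1 (0.387 to 0.530 CPM), Klrb1c (0.850 to 1.27), Gzma (0.803 to 0.842), Eomes (0.272 to 0.424) and Klre1 (0.625 to 1.09), named after their values were seen, were not. No library of NK cells gives the level to expect of these markers, so the test cannot tell. Trophoblast RNA was not told apart either, since the granzyme sum and the trophoblast marker sum over 12 decidual libraries had r = 0.525 (permutation p = 0.0800), rho = 0.462 (p = 0.134) and r = 0.140 without the 2 farthest libraries, in 1 relation tested.

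The remaining results were each flagged by a test of a difference between 2 responses to S100B, and the values are median log2 differences of lists. Nlrp3-/- minus Nlrp3+/+ decidual macrophages differed in the type I interferon (-0.36), trophoblast (-3.88), monocyte (-0.66), inflammatory cytokine (0.18), neutrophil granule (-0.23) and homeostatic (0.18) lists. Uterine macrophages differed in the cell cycle (-0.37), glycolysis (0.50) and homeostatic (0.51) lists. Decidual neutrophils differed in the MHC class II (1.35), erythroid (-4.62), complement (0.55), neutrophil (-0.32), homeostatic (0.76), macrophage (0.86) and endoplasmic reticulum stress (0.58) lists. Uterine neutrophils differed in the macrophage (1.06), erythroid (2.46), neutrophil granule (-0.64) and neutrophil (-0.64) lists, and in Gm28900 (fitted log2 15.07 against groups without a read). Between the decidual and uterine responses of Nlrp3+/+ cells, macrophages differed in the cell cycle (-0.51), type I interferon (0.43), homeostatic (0.44) and glycolysis (0.34) lists, and neutrophils in the erythroid list (6.34) and Gm28900 (fitted log2 14.09). Every list named here passed camera with its preset correlation and none did with an estimated correlation.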

How the results depend on the processing

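S100B in Nlrp3+/+ decidua, the only simulated comparison of 2 neutrophil libraries a side, recovered 0% of 4-fold changes. Its count of 0 thus excludes little. With 3 macrophage libraries a side 48% of 2-fold and 97% of 4-fold changes were recovered. A count of 0 there thus leaves single 2-fold changes open. Recovery was not split by expression level. Of 225 list calls, 25 held with an estimated correlation between genes (2 of them the inflammasome list with Nlrp3 as a member), 216 with DESeq2 size factors, 114 of 131 in a fit of that tissue alone and 23 of 26 in a fit of the compared groups alone. In the 2412 leave-one-out fits of lists 2022 kept the call, 378 lost it and 12 turned it. For single genes, 1370 of 1656 such fits kept sign and side of the threshold. The 8 pooled comparisons, the replicate number as a random effect and the leave-one-out fits of lists were added after the data had been seen. Every planned processing change was run, and a fit that left 1 library on a side took its spread from the other groups. Causes of changes were not tested.

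The DESeq2 test called more genes in every comparison. For S100B against PBS in macrophages it called 24 (Nlrp3+/+ decidua), 22 (Nlrp3-/- decidua), 79 (Nlrp3+/+ uterus), 32 (Nlrp3-/- uterus), 40 (Nlrp3+/+ pooled) and 38 (all), and in neutrophils 545, 669, 432, 1504, 351 and 729 in the same order. For genotype in macrophages it called 57 (S100B decidua), 42 (PBS decidua), 91 (S100B uterus), 166 (PBS uterus) and 433 (all), and in neutrophils 681, 536, 913, 1054 and 934. The genotype difference of the response had 18 and 36 in decidual and uterine macrophages and 494 and 897 in neutrophils. Decidua against uterus had 83 (Nlrp3+/+ PBS) and 1403 (all) in macrophages and 493 and 1233 in neutrophils, and the tissue difference of the response 29 and 324.

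With DESeq2 size factors in edgeR the genotype count in PBS uterine neutrophils went from 1 to 0, and no other count moved by more than 1.5-fold. Without the expression filter the pooled macrophage genotype count went from 68 (20 higher, 48 lower) to 34 (11 and 23) and the neutrophil tissue count from 11 to 25. A fit of that tissue alone kept 2 calls in S100B decidual macrophages but only 1 of the original 2. It took the other macrophage genotype counts to 1 (PBS decidua, from 2), 1 (S100B uterus, from 4) and 1 (PBS uterus, from 2), and took to 0 all neutrophil counts of 1 or 2, that is the 4 genotype comparisons, S100B in Nlrp3+/+ uterus and the genotype difference in uterus. A fit of the compared groups alone took decidua against uterus in Nlrp3+/+ PBS macrophages from 11 to 2 and the tissue difference in neutrophils from 1 to 0.

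Replicate numbers were not shown to pair decidua with uterus. The correlation of residuals at 1 number ran from -0.50 to 0.53 in macrophages (6 of 12 pairs over 0.1) and from 0.01 to 0.07 in neutrophils (0 of 8). With the number as a block the tissue difference of the response in neutrophils had 0 genes in place of 1, and decidua against uterus in Nlrp3+/+ PBS macrophages 8 in place of 11. As a random effect in voom the block gave 37 (18 higher, 19 lower) in place of 68 (macrophage genotype), 893 in place of 855 (macrophage tissue, 763 shared), 23 (18 higher, 5 lower) in place of 11 (5 and 6, neutrophil tissue, 7 shared), 3 and 2 in place of 1 (neutrophil genotype and S100B in Nlrp3+/+) and 2 in place of 0 (S100B over all neutrophils).

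Leaving out 1 library gave these lowest and highest counts. In macrophages they were 0 and 8 for S100B in Nlrp3+/+ uterus, 1 and 3 (S100B) and 1 and 2 (PBS) for genotype in decidua, 2 and 11 (S100B) and 2 and 17 (PBS) for genotype in uterus, 0 and 1 for the genotype difference in uterus, 5 and 31 for decidua against uterus in Nlrp3+/+ PBS, 25 and 173 for pooled genotype and 621 and 1029 for pooled tissue. In neutrophils they were 0 and 1 (Nlrp3+/+) and 0 and 5 (Nlrp3-/-) for S100B in decidua, 0 and 1 and 0 and 443 in uterus, 0 and 1 (S100B) and 0 and 7 (PBS) for genotype in decidua, 0 and 2 and 0 and 407 in uterus, 0 and 1 and 0 and 345 for the genotype difference in decidua and uterus, 0 and 1 for decidua against uterus in Nlrp3+/+ PBS and 0 and 2 for the tissue difference. Pooled neutrophils had 1 and 289 (genotype), 0 and 1 (S100B in Nlrp3+/+), 0 and 234 (S100B) and 0 and 319 (tissue). The other 7 macrophage comparisons stayed at 0. Without Nlrp3 the inflammasome list, tested so after the data had been seen, passed in 1 of 10 genotype comparisons, PBS uterine macrophages (camera adjusted p = 0.0345, adjusted p = 0.222 with an estimated correlation). It lost that call without Nlrp3+/+ replicate 3 (0.269) or Nlrp3-/- replicate 12 (0.0785). Among the lists adjusted with it, lysosome and lipid handling missed the threshold with an estimated correlation in PBS uterine macrophages (adjusted p = 0.0504, from 0.0432), and the monocyte list missed it in S100B decidual macrophages (camera adjusted p = 0.0527, from 0.0494).

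Some directions turned when 1 library was left out. The log2 fold change of Il1b after S100B ran from -0.10 to 0.15 in Nlrp3-/- decidual macrophages, with -0.097 without PBS replicate 12 and -0.0054 without S100B replicate 16. In Nlrp3+/+ uterine macrophages it ran from -0.13 to 0.14, with -0.130 without PBS replicate 2 and -0.094 without S100B replicate 7. For lists the camera adjusted p and its range over the leave-one-out fits follow. Homeostatic genes turned after S100B in Nlrp3+/+ decidual macrophages without S100B replicate 8 (0.751, range 2.49e-07 to 0.767), in Nlrp3-/- uterine macrophages without S100B replicate 16 (0.940, from 6.68e-06) and in the genotype difference of decidual macrophages without Nlrp3+/+ S100B replicate 9 (0.775, from 7.02e-05). Without Nlrp3+/+ PBS uterine replicate 3 the type I interferon list turned after S100B in Nlrp3+/+ uterine macrophages (6.35e-06, range 1.20e-10 to 0.800), in the tissue difference (0.00665, range 1.07e-10 to 0.447) and after S100B in all macrophages (0.266, range 7.76e-06 to 0.357). Without that library the glycolysis list turned between tissues in Nlrp3+/+ PBS macrophages (0.189, range 3.13e-08 to 0.353) and in the tissue difference (0.984, from 3.47e-05). NK markers turned after S100B in Nlrp3-/- uterine macrophages without S100B replicate 17 (0.758, from 7.50e-06), and T cell markers between tissues without uterine replicate 2 (0.976, from 0.00108). Without Nlrp3+/+ S100B decidual replicate 5 the erythroid list turned after S100B in Nlrp3+/+ decidual neutrophils (0.247, range 2.18e-10 to 0.597) and in the genotype difference there (0.277, range 2.09e-08 to 0.537).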

Other observations

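The levels of the transcripts that NLRP3 acts through are given here for macrophages and neutrophils, which were scaled apart and not tested against each other. Over all PBS libraries Il1b stood at 992 ± 266 CPM in macrophages (n = 12) and 16048 ± 3064 CPM in neutrophils (n = 8), and after S100B at 1027 ± 136 and 15420 ± 3118 CPM. Casp1, the protease of the inflammasome, stood at 54.0 ± 6.65 CPM in macrophages and 20.5 ± 10.13 CPM in neutrophils under PBS, and Pycard, its adaptor, at 36.0 ± 3.97 and 16.2 ± 8.94 CPM. Ptgs2, which makes the prostaglandins of labour, stood at 13.2 ± 7.52 CPM in macrophages and 769 ± 217 CPM in neutrophils under PBS, and at 12.8 ± 4.46 and 742 ± 166 CPM after S100B. None of these genes was called after S100B in the pooled libraries of either cell type (edgeR).

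The Ptgs2 level of Nlrp3-/- macrophages, 10.23 ± 2.95 against 15.9 ± 7.11 CPM in Nlrp3+/+ over all groups, was not called (n = 12 each, log2 -0.67 ± 0.20, edgeR adjusted p = 0.163). In decidual neutrophils Tnf stood at 181 ± 45.4 CPM and Il1a at 142 ± 71.2 CPM, against 334 ± 124 and 271 ± 103 CPM in uterine neutrophils (n = 8 each, edgeR adjusted p = 0.419 and 0.544).

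Other splits of the libraries were put through the same test to see how many genes a grouping without meaning calls. All of these tests were chosen after the counts had been seen, first with 24 splits and then with 100. The real count came out highest for genotype in all macrophages (68 against at most 2 elsewhere, reached in 1 of 100 splits), for tissue in all macrophages (855 against at most 3, 1 of 100) and for tissue in all neutrophils (11 against at most 3, 1 of 100). For genotype in all neutrophils 14 of 100 splits gave at least the real 1, with up to 4, and for S100B in Nlrp3+/+ neutrophils 10 of 18 splits gave at least the real 1, with up to 2. Where the real count was 0 every split reached it, 100 of 100 each. The highest other counts there were 1121 and 2 (genotype difference, decidual and uterine macrophages), 1014 (tissue difference, macrophages), 1456 and 683 (S100B in Nlrp3+/+ and in all macrophages) and 6 (S100B in all neutrophils). Comparisons of 3 against 3 libraries have only 10 splits, which cannot give a share under 0.05. There the real count was reached in 1 of 10 splits for decidua against uterus in Nlrp3+/+ PBS (11, at most 0 elsewhere) and for genotype in decidua (2 and 2 after S100B and PBS, at most 1 and 0) and uterus (4 and 2, at most 1 and 0). It was reached in 10 of 10 for the S100B comparisons, all with a real 0 that any split reaches (at most 2 and 0 in decidua and 2 and 1 in uterus, Nlrp3+/+ and Nlrp3-/-).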
